A study of Mus musculus with 6 samples.

How the data were processed

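Messenger RNA of the nasomaxillary complex of E17.5 mouse embryos was measured in 6 libraries, 3 control (floxed Pth1r) and 3 mutant (floxed Pth1r with Wnt1-Cre), grouped by the genotype label. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a stranded messenger RNA kit. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18 and Cuffdiff 2.2.1 with genome build mm10. The annotation, filters and strand setting are not given in the sources used here.

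The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), one per gene symbol, per the file headers. All 6 files held the same 24346 symbols, of which 3460 were at 0 in every library. The third quartile of FPKM lay between 15.76 and 15.83 in every library. Whether the authors scaled libraries to each other is not given. FPKM of very short genes is unstable: 59 genes were at 0 in at least 1 library with over 5 FPKM in another, and 44 of these had symbols of microRNAs or other small RNAs.

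FPKM values are not counts, so no count test was used. Low values of a gene are whole multiples of what 1 fragment is worth, and ratios of such values under 0.15 FPKM between libraries gave relative library sizes of 1.0, 1.11 and 0.938 for control replicates 1 to 3 and 1.02, 0.903 and 0.671 for mutant replicates 1 to 3. In the libraries other than control replicate 1, the reference, between 36.2% and 41.7% of the low genes lay at the commonest ratio. Between 89.3% and 94.7% stood at ratios of small whole numbers relative to it, within a tolerance of 0.01. The value of 1 fragment and the annotated length of 74 genes put control replicate 1 at about 13000000 fragments (quartiles 11600000 and 13300000), which is an estimate and not a deposited depth. Mutant replicate 3 was the shallowest, so its low values are the least precise. Pearson r of log2 values between libraries, across genes, was 0.986 to 0.991, and no 2 libraries were identical.

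Values were analysed as log2(FPKM + 1) without further scaling, for 14766 genes with a mean of at least 1 FPKM over the 6 libraries. Mutant was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, no covariate), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. This leaves 4 residual degrees of freedom. The 27 gene lists held 370 distinct genes in 383 memberships, of which 380 were in the files, 3 of them under an older symbol (Lect1, 3110079O15Rik and Epb4.2). Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Members were also adjusted over the list alone. Gene positions are from the GENCODE annotation of GRCm38, the same coordinates as mm10.

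The genes named in the text follow a rule fixed before the data were examined. It takes Pth1r and Pthlh. It takes up to 10 called genes with the largest rise and 10 with the largest fall whose groups do not overlap. From each list it takes up to 4 called members, or the 2 members of smallest p where none is called. It gave 60 genes, of which 2 are not reported here. Other genes are named as chosen after their values were seen. FPKM values are means ± SD over 3 libraries, and log2 changes are given ± SE.

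The fit was tested on simulated data made from the real means and residual SDs of the 14766 genes, with 200 genes changed, in 10 draws. It recovered 93.9% of genes changed by 2-fold and 98.8% of those changed by 4-fold on the log2(FPKM + 1) scale, and 4.76% of the calls were false. With no gene changed it called 0 genes and an average of 0.40 lists per draw. The simulation gives genes independent noise, which the real libraries do not have. The changed genes were drawn at random, so the recovered shares are averages and do not hold for genes that vary more between libraries.

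The alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, median ratio, upper quartile and quantile scaling, rescaling without erythroid and muscle genes, eBayes without trend or robust, library weights, an adjusted p under 0.1, a fold of at least 1.5, an estimated correlation, fry, and leaving out each library. Sex as a covariate, female libraries alone, the muscle list as a covariate and leaving out small RNAs were added after seeing the data. Plots were drawn with matplotlib in Python.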

Results

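The nasomaxillary complex, the block of bone, cartilage and soft tissue that forms the nose and upper jaw, was collected from E17.5 mouse embryos and profiled by messenger RNA sequencing. The 3 control libraries came from embryos carrying floxed copies of Pth1r, the gene for the receptor of parathyroid hormone and parathyroid hormone-related protein. The 3 mutant libraries came from embryos with the same floxed gene and Wnt1-Cre, a transgene that drives recombination in cells of the neural crest, from which most of the facial skeleton derives. Each library gave one FPKM value for each of 24346 gene symbols. Total FPKM ran from 514693 to 546322 per library, and between 14620 and 14787 genes had at least 1 FPKM. The spacing of low values put depth at about 13000000 fragments in control replicate 1, 14500000 and 12200000 in control replicates 2 and 3, and 13300000, 11800000 and 8800000 in mutant replicates 1, 2 and 3. The labels do not say whether libraries came from separate embryos or litters, so p-values measure only the spread between these samples. Mutant and control are used below as the labels give them.

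The comparison asked which genes differ in the nasomaxillary complex between embryos with floxed Pth1r and Wnt1-Cre and embryos with floxed Pth1r alone. The controls carry no Cre, so for every change below an effect of the transgene cannot be told apart from loss of Pth1r. Pth1r itself (chromosome 9, 110722085 to 110747145, minus strand, GRCm38) measured 68.0 ± 11.1 FPKM in control (SD, n = 3) and 75.1 ± 4.73 FPKM in mutant (SD, n = 3). Its values were 75.2, 55.2 and 73.5 FPKM in control replicates 1 to 3 and 77.3, 78.4 and 69.7 FPKM in mutant replicates 1 to 3. The log2 change was 0.15 ± 0.12 (SE), with a limma adjusted p of 0.686. Leaving out each library in turn gave changes from 0.013 to 0.23. The labels do not say which part of the gene is floxed, and the tissue also holds cells outside the neural crest, so a value for the whole gene does not check the genotype labels.

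In a list of 22 cartilage matrix and early chondrocyte genes, 21 had negative changes in mutant libraries. Of them 9 fell at a limma adjusted p under 0.05 over all genes. Col10a1, the collagen made by hypertrophic chondrocytes, rose. The count of cartilage genes past that threshold was 2 without any one control or without mutant replicate 1. It was 6 without mutant replicate 2 and 14 without mutant replicate 3. The list as a set was lower at a preset correlation but had an adjusted p of 0.309 with an estimated correlation. Col10a1 (chromosome 10, 34389981 to 34397085, plus strand, GRCm38) rose from 1.26 ± 0.0371 FPKM in control to 64.4 ± 11.5 FPKM in mutant (SD, n = 3 each), 51.2 times the control mean. Col2a1, the main collagen of cartilage, fell from 702 ± 88.3 FPKM to 182.5 ± 67.5 FPKM, so that the control mean was 3.85 times the mutant mean. Matn1, which encodes the cartilage matrix protein matrilin 1, fell from 68.8 ± 4.46 FPKM to 10.5 ± 4.65 FPKM. Pthlh, the gene for parathyroid hormone-related protein and so a ligand of the floxed receptor, rose from 6.63 ± 0.594 FPKM to 11.6 ± 0.668 FPKM.

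Over 14766 genes with a mean of at least 1 FPKM, limma called 39 at an adjusted p under 0.05, of which 9 were higher and 30 lower in mutant. In all 39 the mutant values lay entirely on one side of the control values. Over all tested genes 2512 (17%) were separated in this way, against 10% expected by chance for 3 against 3. At an unadjusted p under 0.05 there were 1670 genes, with 738 expected if nothing changed. With sex as a covariate, chosen after seeing the data, 759 genes had an unadjusted limma p under 0.05, near the number expected. That fit sets the 1 female mutant against the 3 female controls with fewer residual degrees of freedom, so the drop cannot be assigned to sex. The means of FPKM differed by at least 2-fold for 5 of the genes called higher and 16 of those called lower, counting Mir6363, which was listed at 0 in mutant. Log2 changes here are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM.

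The genes that rose, besides Col10a1 (log2 change 4.84 ± 0.12 SE, adjusted p = 1.18e-05), were these. Krtap13, a keratin-associated protein gene, changed by 2.17 ± 0.26 from a control mean of 0.167 FPKM. Sost, which encodes the Wnt inhibitor sclerostin made by osteocytes, changed by 1.41 ± 0.15, from 2.42 to 8.19 FPKM. Sostdc1, a secreted inhibitor of BMP and Wnt signalling, went from 35.2 to 65.6 FPKM, and Hhip, a target and inhibitor of hedgehog signalling, from 4.47 to 9.03 FPKM. Cbfa2t2, a transcriptional corepressor gene (chromosome 2, 154436481 to 154539356, plus strand), went from 10.6 ± 0.587 to 21.3 ± 1.70 FPKM, a log2 change of 0.95 ± 0.073 with an adjusted p of 0.00633. The next tested genes on that chromosome, Necab3 and E2f1, chosen after their values were seen, had log2 changes of -0.51 and -0.46 (limma adjusted p of 0.260 and 0.0659). Pthlh changed by 0.72 ± 0.079 on the log2 scale (adjusted p = 0.0228), AU021063 by 0.59 ± 0.073, and Penk, which encodes the opioid precursor proenkephalin, by 0.45 ± 0.061. Several of these calls were lost under other settings. Over 21 alternatives Pthlh stayed called in 12 (limma adjusted p up to 0.199), AU021063 and Penk in 10 each (up to 0.477 and 0.587), Sost in 13, Sostdc1 in 14, Hhip in 18 and Cbfa2t2 in 19, and Krtap13 in 13 of 20. Pthlh lost its call when any one library but mutant replicate 2 was left out, and AU021063 and Penk when any one library was.

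Of the genes that fell, Ucma, a gene of growth plate cartilage, dropped from 8.24 ± 1.15 to 0.800 ± 0.0753 FPKM, a log2 change of -2.35 ± 0.11 with an adjusted p of 0.000567. Epyc, which encodes the cartilage proteoglycan epiphycan, dropped from 16.0 ± 0.222 to 3.34 ± 0.534 FPKM. Lect1, the gene of chondromodulin, went from 108 to 23.4 FPKM. Matn1 changed by -2.68 ± 0.25, Mfi2, the gene of melanotransferrin, by -2.29 ± 0.16, and Scrg1 by -1.99 ± 0.18. Col9a1 and Col9a3, both collagen IX genes of cartilage, changed by -1.68 ± 0.22 and -1.65 ± 0.19. Over 21 alternatives Col2a1 and Col9a3 stayed called in 12 each, Col9a1 in 11, Matn1 in 14, Lect1 in 15, Scrg1 in 17, Mfi2 in 20 and Epyc in all 21, and Ucma in all 20 that tested it. Col2a1 lost its call without control replicates 1, 2 or 3 or mutant replicate 1 (limma adjusted p up to 0.335 over all alternatives). The gene with the largest fitted fall was a microRNA precursor, Mir6363 (chromosome 16, 50727132 to 50727245). It measured 190.3, 515 and 1014 FPKM in control replicates 1 to 3 and was listed at 0 in all 3 mutant libraries. After allowing for library size the control values stood as 1 to 3 to 5, the pattern of very few fragments on a short gene.

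**Figure D1:**
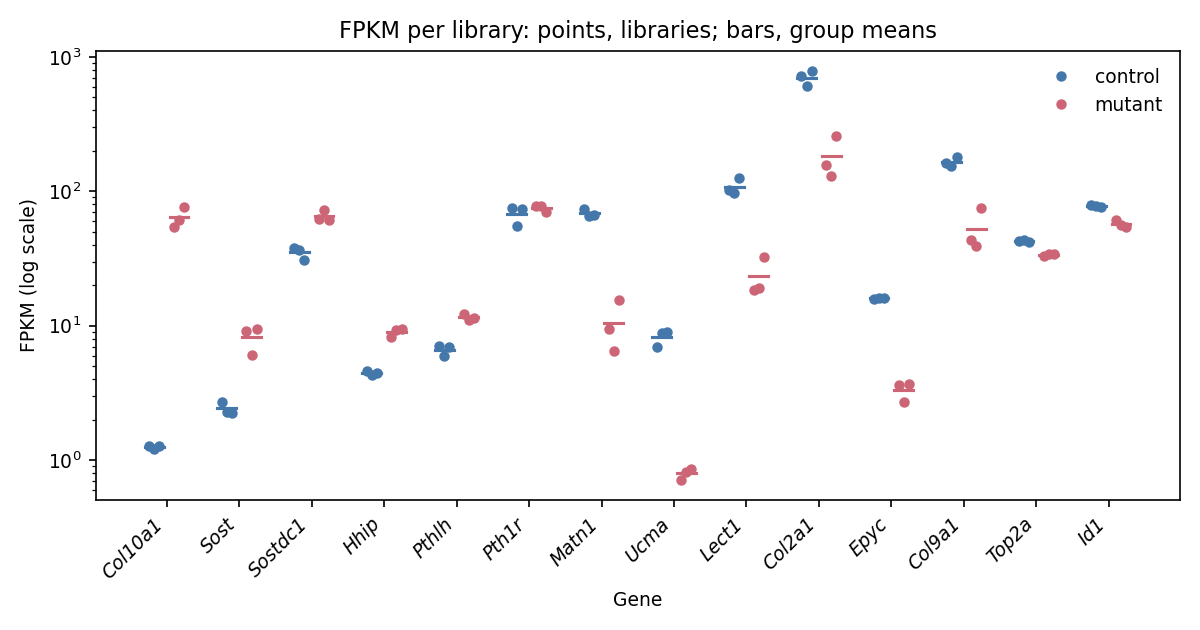
FPKM of 14 named genes in each library on a log axis, with control libraries in blue, mutant libraries in red and a bar at each group mean. Col10a1 lies near 1.26 FPKM in the controls and between 54.5 and 77.0 FPKM in the mutants, Pth1r overlaps between groups, and the cartilage genes Matn1, Ucma, Lect1, Col2a1, Epyc and Col9a1 lie lower in every mutant library.

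The gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01. In the list of cartilage matrix and early chondrocyte genes, 21 of 22 members had negative changes, with a median log2 change of -1.10. Of them 9 fell at an adjusted p under 0.05 over all genes, namely Ucma, Epyc, Matn1, Lect1, Col2a1, Col9a1, Col9a3, Acan and Col11a1, the last 2 being named after their values were seen, and 20 fell when adjusted over the list alone. The remaining members, Sox6 and Chad, named after their values were seen, had log2 changes of -0.10 and 0.018 and passed neither adjustment. The 9 calls became 2 without control replicate 1, 2 or 3 or mutant replicate 1, 6 without mutant replicate 2, 14 without mutant replicate 3, and 4 with no filter or without trend. They became 5 with robust eBayes, 13 with library weights and 2 with sex or the muscle list as a covariate, and 21 or 22 of the changes were negative in each of these fits. With the muscle list, itself higher in mutant like the skin list, as a covariate, the median change was -0.962. The list was lower by camera (adjusted p = 1.61e-28). With an estimated correlation its adjusted p was 0.309, the highest of 23 alternatives, which reached down to 6.09e-38. By fry, which asks whether the members move one way, its adjusted p was 0.0261.

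Among 12 tested hypertrophic chondrocyte genes only Col10a1 was called. Adjusted over the list alone 3 were higher and 2 lower. The higher ones were Col10a1, Mef2c (log2 change 0.32) and Ihh (0.66), and the lower ones Scin (-0.59) and Mmp13. Of these Mef2c, Ihh and Scin were named after their values were seen. Mmp13, a collagenase of late hypertrophic cartilage and of bone, measured 76.2 ± 35.5 FPKM in control and 37.7 ± 3.22 FPKM in mutant (limma adjusted p = 0.318). The list was not called (adjusted p = 0.532), and its median of -0.065 and mean of 0.31 differed in sign. The list of the parathyroid hormone-related protein and hedgehog loop was higher by camera (adjusted p = 0.000204), with Hhip and Pthlh called among 14 members and 6 members higher when adjusted over the list alone. With an estimated correlation its adjusted p was 0.485, and over its 23 alternatives the adjusted p began at 3.15e-05. It was called in 20 of 23, its call being lost with the estimated correlation, with fry and with the muscle list as a covariate. The median change of its members was 0.038 and 4 of them had negative changes. Of 13 genes that respond to cyclic AMP, the second messenger of the receptor, none was called. The list's adjusted p was 0.0893. It was called higher in 3 of 23 alternatives, namely with no filter, with a mean of at least 5 FPKM and without mutant replicate 1 (adjusted p from 0.0176 to 0.662 over all 23), and Sik1 and Fos had log2 changes of 0.26 and 0.34.

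Bone lists moved in both directions. In the osteoblast and bone matrix list 19 of 20 members had negative changes (median -0.27). None was called over all genes and 4 were lower when adjusted over the list alone. Bglap and Bglap2, which encode osteocalcin, measured 17.6 ± 9.26 and 19.4 ± 9.65 FPKM in control against 5.61 ± 1.74 and 6.22 ± 2.82 FPKM in mutant, with limma adjusted p of 0.233 and 0.234. Camera called the list lower (adjusted p = 3.54e-08), but with an estimated correlation the adjusted p was 0.485, and its alternatives began at 1.15e-15. The osteocyte list was higher by camera (adjusted p = 0.0127, and 0.485 with an estimated correlation, from 0.000516 over the alternatives). Of its 5 members Sost was called, 3 had positive and 2 negative changes, and 3 were higher when adjusted over the list alone. The list stayed called in 15 of 23 alternatives. Its call was lost with no filter, with a mean of at least 5 FPKM, without control replicate 2, without mutant replicate 3 and with sex as a covariate, among others. The osteoclast list was not called (adjusted p = 0.506, 0 of 14 members, Ostm1 and Oscar at 0.13 and 0.19), nor were matrix proteases and their inhibitors (adjusted p = 0.486, 0 of 15 members, 1 lower when adjusted over the list alone). In the latter list Timp1 measured 76.8 ± 21.5 FPKM in control and 41.0 ± 3.07 FPKM in mutant.

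Of 19 Wnt pathway genes Sostdc1 and Sost were called higher and Sfrp4, a secreted Wnt antagonist, lower (22.4 ± 4.22 to 8.54 ± 1.43 FPKM, called in 11 of 21 alternatives). The list itself was not called (adjusted p = 0.747), and its median of -0.026 and mean of 0.083 differed in sign. Adjusted over the list alone 4 were higher and 2 lower. The BMP list was lower (adjusted p = 0.0284, and 0.656 with an estimated correlation, from 0.00544 over the alternatives), with 11 of 14 changes negative. It was called in 15 of 23 alternatives, and its call was lost with library weights, without control replicate 1, mutant replicate 2 or mutant replicate 3, and with sex as a covariate, among others. Its only called member, over all genes and adjusted over the list alone, was Id1, a direct BMP target, which fell from 77.5 ± 1.43 to 57.5 ± 3.86 FPKM and was called in 10 of 21 alternatives. All 20 proliferation genes had negative changes (median -0.31), 13 of them past the threshold when adjusted over the list alone, and 1, Top2a, over all genes. Top2a, a topoisomerase of dividing cells, fell from 42.4 ± 0.773 to 33.6 ± 0.697 FPKM and was called in 7 of 21 alternatives. Camera gave the list an adjusted p of 3.80e-14 and fry 0.0208. With an estimated correlation its adjusted p was 0.309, and over its alternatives the adjusted p began at 1.27e-15. Among tendon and ligament genes Fmod, which encodes fibromodulin, fell from 56.7 to 32.2 FPKM, a log2 change of -0.79 ± 0.093 called in 12 of 21 alternatives, and the list was not called (adjusted p = 0.311). The craniofacial transcription factor list was not called either (adjusted p = 0.311), with log2 changes of -0.38 for Six2 and -0.58 for Barx1.

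**Figure D2:**
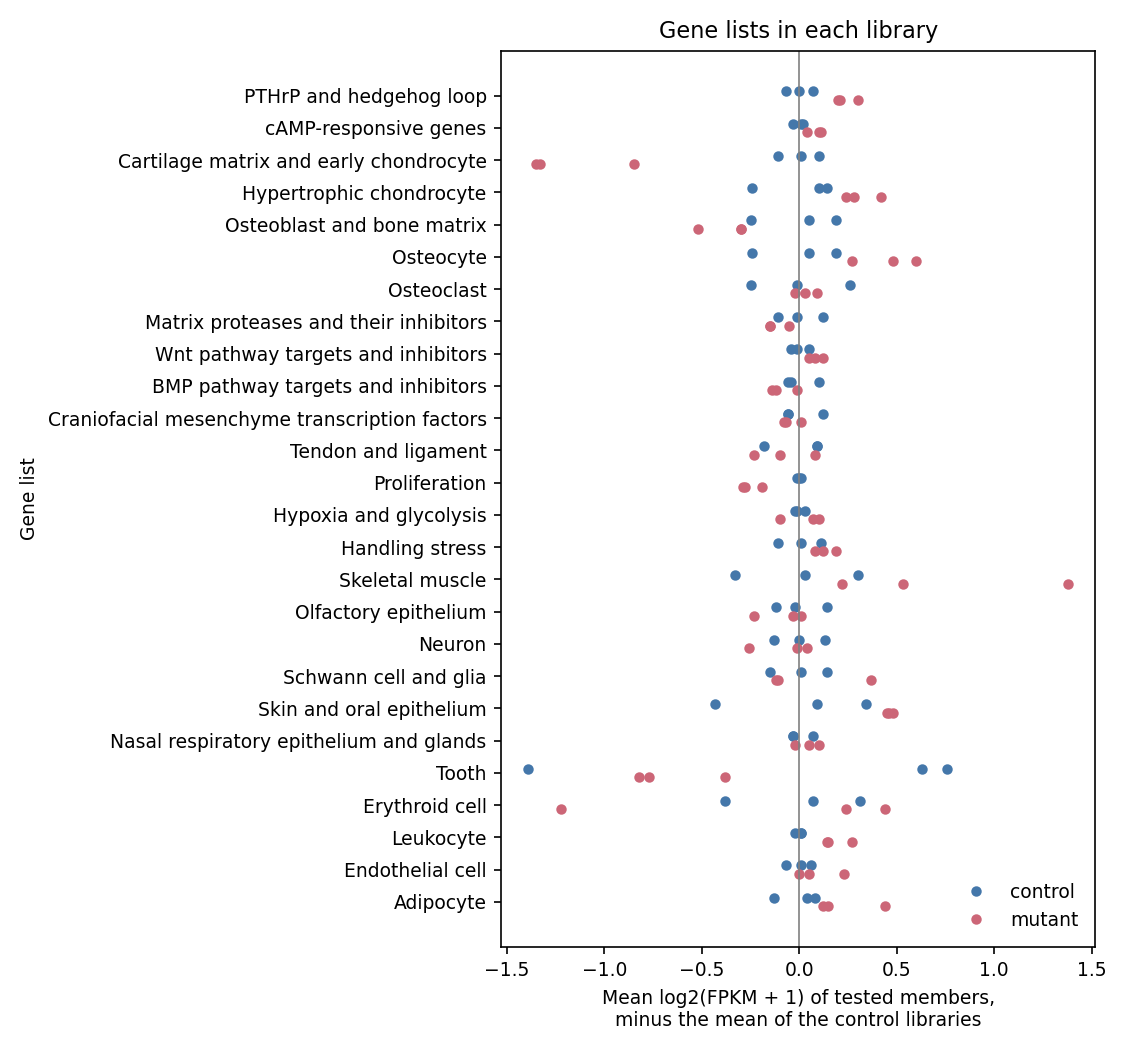
Mean log2(FPKM + 1) of the tested members of each gene list in each library, minus the mean of the 3 controls, with control libraries in blue and mutant libraries in red. The cartilage list lies at -1.33, -1.35 and -0.85 in the mutant libraries and the proliferation list at -0.28, -0.19 and -0.29, while the skeletal muscle list reaches 1.38 in mutant replicate 2 and overlaps between groups.

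Markers of other tissues in the dissection also differed between libraries. The skeletal muscle list was higher by camera (adjusted p = 7.04e-09, and 0.501 with an estimated correlation), all 20 members had positive changes, none was called over all genes and 3 were higher when adjusted over the list alone. It was called in 19 of 22 alternatives, its call being also lost with fry and, by construction, with itself as a covariate. Its library means, relative to the control mean, were 0.30, -0.33 and 0.03 in control and 0.53, 1.38 and 0.22 in mutant. Myod1, a muscle transcription factor, measured 2.43 ± 0.701 FPKM in control and 6.43 ± 3.02 FPKM in mutant, and Tnni1 28.4 ± 2.98 and 58.7 ± 23.6 FPKM. The skin and oral epithelium list was higher (adjusted p = 5.90e-05, and 0.485 with an estimated correlation), with library means of 0.34, 0.09 and -0.43 in control and 0.46, 0.45 and 0.48 in mutant. Of its 15 tested members 13 had positive changes, 0 were called over all genes and 5 were higher when adjusted over the list alone. In it Krt5 measured 172 ± 54.0 and 285 ± 10.1 FPKM, and Krt15 158 ± 21.4 and 219 ± 4.85 FPKM. The leukocyte list (adjusted p = 0.000179, and 0.309 with an estimated correlation) and the endothelial list (adjusted p = 0.0284, and 0.700 with an estimated correlation) were higher with no member called over all genes or adjusted over the list alone. Positive changes were seen in 13 of 13 leukocyte and 10 of 11 endothelial members. The leukocyte list was called in 20 of 23 alternatives and lost its call with the muscle list as a covariate, among others. The endothelial list was called in 15 of 23 alternatives, and its call was lost with library weights, without control replicate 2 or mutant replicate 2, and with sex as a covariate, among others. S100a9 and S100a8 had log2 changes of 0.44 and 0.39, and Tek and Tie1 changes of 0.23 and 0.17.

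The other lists were not called by camera, and none of their members passed the threshold over all genes except S100b. Adjusted p was 0.629 for hypoxia and glycolysis (Egln3 0.15 and Adm 0.24 on the log2 scale), 0.137 for handling stress (Hspb1 0.32), 0.949 for olfactory epithelium (Neurog1 -0.55) and 0.715 for neurons (Tubb3 -0.30 and Elavl4 -0.43). It was 0.486 for nasal respiratory epithelium and glands (Muc5b 0.21 and Bpifa1 0.15), 0.120 for adipocytes (Lpl 0.58 and Pparg 0.27), 0.949 for erythroid cells (Hbb-bs -1.30 and Slc4a1 0.24) and 0.933 for tooth genes. Adjusted over the list alone 1 adipocyte gene was higher, and 0 genes passed in the hypoxia, stress, olfactory, neuron, respiratory, erythroid and tooth lists. The olfactory, erythroid and tooth lists had a test direction above 0 and a mean below 0. In the Schwann cell and glia list (adjusted p = 0.638) S100b, a gene of glia and also of chondrocytes, fell from 17.8 ± 0.941 to 10.1 ± 0.418 FPKM. Of the tooth genes Amelx, which encodes an enamel protein, measured 55.6 ± 47.4 FPKM in control and 0.549 ± 0.826 FPKM in mutant (limma adjusted p = 0.358). Amelx was called in 1 of 21 alternatives, and leaving out each library in turn gave log2 changes from -5.88 to -3.13.

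Sex differed between the groups. Xist, expressed from the inactive X chromosome and named after its values were seen, measured 74.4, 74.1 and 74.0 FPKM in control replicates 1 to 3 and 77.1 FPKM in mutant replicate 1, and 0.03 FPKM in mutant replicates 2 and 3. The Y-linked genes Ddx3y and Eif2s3y were at 15.1 and 33.1 FPKM in mutant replicate 2, at 14.1 and 36.1 FPKM in mutant replicate 3, and at 0 in the other 4 libraries. The sex-linked list had an adjusted p of 0.0594, with 4 genes higher and 1 lower when adjusted over the list alone. With sex as a covariate, chosen after seeing the data, limma called 5 genes higher and 5 lower. No list stayed called with an estimated correlation. Other splits of the same 6 libraries into 3 and 3 called 6 to 16 lists by camera at the preset correlation, against 10 for control and mutant. The counts also moved with single libraries: 10, 14 and 13 genes were lower without control replicates 1, 2 and 3 and 16 without mutant replicate 1, while 3 were higher without control replicate 2 and 14 without mutant replicate 3.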

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

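No paired analysis was possible because the labels give no replicate numbers, and the numbers used here follow the order of deposit within each group, so they match no control to a mutant. All 39 called genes kept their direction under every alternative that tested them. Their mutant and control values did not overlap, so leaving out a library, another pseudocount or library weights could not reverse them. Pth1r was called under none of 21. The calls were less stable: of the 39, 17 stayed called with no filter, 19 without trend, 7 with sex as a covariate and 5 with the muscle list as a covariate. Without control replicates 1, 2 and 3, 13, 15 and 13 stayed called, and without mutant replicates 1, 2 and 3, 16, 25 and 27. Col10a1 and Epyc stayed called in all 21 alternatives that tested them, and Ucma and Mir6363 in all 20. The values of Mir6363 have the pattern of very few fragments on a short gene, so its kept call says little. Pthlh and Col2a1 were called in 12 of 21, Col9a1 and Sfrp4 in 11, Penk, AU021063 and Id1 in 10 and Top2a in 7. The median log2 change of all genes was at most 0.0274 under any scaling, when erythroid and muscle genes were left out. The lower depth of mutant replicate 3 limits genes at low FPKM. The sex, female, muscle and small RNA alternatives were chosen after seeing the data. The cause of the changes below was not tested. Fits that left out a library had less data and the fit with no filter adjusted over more genes. Loss of power was not separated from dependence on single libraries.

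Against 9 genes higher and 30 lower, limma called 3 and 15 with no filter, 5 and 14 without trend, 18 and 53 with library weights, and 19 and 61 at an adjusted p under 0.1. With sex as a covariate it called 5 and 5, and with the muscle list as a covariate 1 and 4. In female libraries only, 3 control and 1 mutant, 18 were higher, the lone mutant being assumed to vary like the controls. Leaving out one library gave 3 to 14 higher and 10 to 30 lower. Without control replicates 1, 2 and 3 there were 10, 14 and 13 lower, and 16 without mutant replicate 1. Without control replicate 2 there were 3 higher, and 14 without mutant replicate 3. Against 6 lists higher and 4 lower, an estimated correlation called 0 and 0, fry called 0 and 2, and the muscle list as a covariate gave 7 lower. Of the lists not called, the osteoclast and tooth lists were called without control replicate 3, handling stress without control replicate 1, the sex-linked list without mutant replicate 1, and tendon and hypoxia without mutant replicate 2 and with the muscle covariate. Protease, craniofacial, olfactory, neuron and erythroid lists were called with the muscle covariate alone.

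The following values changed sign, and of these the endothelial list alone was called in the reported comparison. With the muscle list as a covariate the log2 change was -0.021 for Pth1r, -0.024 for Oscar, 0.030 for Tubb3, 0.071 for Elavl4 and 1.12 for Hbb-bs. In the same fit list means were 0.090 for olfactory epithelium, 0.13 for neurons, -0.13 for Schwann cells and glia, 0.66 for erythroid cells and -0.037 for endothelial cells, and the muscle list itself was fixed at 0. With sex as a covariate Hbb-bs was 0.75, and list means were 0.0066 for craniofacial transcription factors, 0.0088 for olfactory epithelium, -0.11 for Schwann cells and glia and 0.44 for erythroid cells. Female libraries only gave the same values but for Schwann cells and glia, at -0.13. With library weights Schwann cells and glia were at -0.0092 and erythroid cells at 0.11, and with a mean of at least 5 FPKM the sex-linked list was at -0.34. Leaving out one library gave -2.32 to 0.40 for Hbb-bs, -0.54 to 0.34 for erythroid cells, -0.11 to 0.13 for Schwann cells and glia, -0.081 to 0.010 for craniofacial transcription factors, -0.093 to 0.16 for osteoclasts and -0.014 to 0.083 for hypoxia and glycolysis.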

Other observations

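The tests with sex as a covariate, with the muscle list as a covariate, of members against the list mean, on chromosome 2, on E2f1, of the correlation between muscle genes and of the count of genes over splits were chosen after their results were seen, as was the use of the planned values of Col10a1 and of the hypertrophic list to weigh explanations. Of the called genes, 20 stood in no list, 16 lower and 4 higher. The following lower ones fall outside the rule for named genes and were chosen after their values were seen. Susd5 went from 24.2 ± 2.42 FPKM in control to 7.21 ± 2.21 FPKM in mutant, Clec3a, a lectin gene expressed in cartilage, from 8.71 ± 1.18 to 2.16 ± 0.512 FPKM, and Chadl, which encodes a chondroadherin-like protein, from 7.63 ± 0.294 to 3.53 ± 0.354 FPKM. Mia, a secreted protein gene of cartilage, went from 73.5 ± 1.21 to 41.1 ± 0.846 FPKM, and Mgp, an inhibitor of calcification, from 593 ± 27.7 to 370.0 ± 22.8 FPKM. Wwp2, a ubiquitin ligase gene that hosts a microRNA of cartilage, went from 67.7 ± 6.46 to 37.2 ± 2.28 FPKM (n = 3 in each group). Amelx differed between control libraries, at 81.4, 84.4 and 0.88 FPKM.

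The 39 called genes compare with at most 3 in any other of the 10 splits of the 6 libraries into 3 and 3, and 1 of the 10, the real one, gave as many. Every other split mixes controls and mutants in both groups, so a real difference would add to the spread within them. Their few called genes therefore do not measure what chance gives. The 10 lists called by camera compare with 6 to 16 in the other splits, and 3 of the 10 splits, the real one included, gave at least 10. Every split called at least 6 lists, so a camera call at the preset correlation does not by itself set control against mutant apart from other splits. With 10 splits no share under 0.05 can be had for either count.

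The first pattern is the fall of cartilage genes with the rise of Col10a1. Sex of the embryos as the whole of it is argued against by the fit with sex as a covariate, in which Col10a1 still changed by 4.62 ± 0.13 (adjusted p = 0.000158, and 2.00e-06 to 0.000516 over all alternatives) and 20 cartilage members were lower when adjusted over the list alone (median change -1.34 against -1.10 without the covariate), though this fit sets the 1 female mutant against the 3 female controls and its calls over all genes went from 9 to 2 with 1 residual degree of freedom fewer and a median SE of 0.185 against 0.170. More muscle as the whole of the cartilage fall is argued against by the fit with the muscle list as a covariate, in which 19 members stayed lower when adjusted over the list alone (median change -0.962 against -1.10), while calls over all genes went from 9 to 2 with a smaller change, 1 residual degree of freedom fewer and a median SE of 0.207 against 0.170. Less cartilage of the same makeup in the mutant dissections would lower Col10a1 too, and its change was 4.84. A larger share of skin, whose list was higher in mutant, was weighed from library means after they were seen, and no fit was made. Skin means were 0.34, 0.09 and -0.43 in control and 0.46, 0.45 and 0.48 in mutant. Cartilage means were 0.01, -0.11 and 0.10 in control and -1.33, -1.35 and -0.85 in mutant. Cartilage thus did not follow skin among controls, which argues against skin as the whole of the cartilage fall. A part played by skin stays open. For the fall itself less cartilage also stays open: 15 of 22 members changed by more or less than the list mean, but members also made in other tissues would do so, so it cannot be told apart from lower expression per cell. A hypothesis is that chondrocytes of the mutant turn hypertrophic early, which may lower early cartilage genes and raise Col10a1. The hypertrophic list as a set had a camera adjusted p of 0.532, which leaves it open. That list shares Alpl, Ibsp and Phospho1 with the osteoblast list, in which 19 of 20 members had negative changes. Those shared members cannot test hypertrophy apart from a change in bone genes. The overlap does not account for the whole set, since its unshared members besides Col10a1 also moved both ways. Ihh, Mef2c, Cd200 and Vegfa had log2 changes of 0.66, 0.32, 0.20 and 0.022. Mmp13, Scin, Panx3 and Runx3 had log2 changes of -0.90, -0.59, -0.089 and -0.052.

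The second pattern is on chromosome 2, where Cbfa2t2 and the next 2 tested genes, Necab3 (154544399 to 154558890, log2 change -0.51 ± 0.13, adjusted p = 0.260) and E2f1 (154559407 to 154569892, -0.46 ± 0.068, adjusted p = 0.0659), had unadjusted p of 3.00e-06, 0.00610 and 0.000237 in limma, while 0 of the 6 tested genes on each side had an unadjusted p under 0.05. A hypothesis is an effect on this stretch alone, such as an inserted transgene, since one Wnt1-Cre line is described as carrying its transgene at E2f1; the labels do not name the line and the controls carry no Cre. The run of 3 ranked 4 among 14559 runs of neighbouring tested genes, a test tried first that ignores how the run was noticed. Of 14580 neighbouring pairs 19 were as strong as Necab3 and E2f1, that pair included. At that rate, with 3 pairs counted for each, 0.152 such pairs would lie beside the 39 called genes. The rate is taken from the observed changes, so it does not measure chance alone, and chance is not excluded. Lower E2f1 could in turn lower proliferation genes: the replication members, targets of E2F factors, had a mean change of -0.15 against -0.34 for the mitosis members, which decides nothing, since the members were split after their values were seen, genes measured in the same libraries are not independent and E2F factors also act on mitosis genes. The reverse, lower proliferation bringing E2f1 down, also stays open, since E2f1 changed by -0.056 relative to the list member that fell furthest.

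The third pattern is the higher skeletal muscle list. More muscle in some dissections is consistent with an estimated correlation of 0.878 between members within groups, with library means that overlap between groups, and with a list mean change of 0.37 without mutant replicate 2 against 0.71 with it. An effect of genotype on muscle was not tested and stays open.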
